A study of Mus musculus with 6 samples.

How the data were processed

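RNA was extracted from RAW264.7 cells with TRIzol and made into sequencing libraries with a commercial kit, per the labels' protocols. The labels give the cell line, the cell type macrophage and bone marrow as the source. The 6 samples form 2 groups by the treatment in the labels, DMSO (n = 3) and NBIF at 8 µM (n = 3), and replicate numbers come from the sample titles. The agent that induced osteoclast formation is not given in the sources used here.

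The authors deposited 1 table of FPKM values, with 1 value per gene symbol and sample. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 without saying what each was used for. They name the human genome build GRCh38, while 97.9% of the symbols in the table were found among mouse gene names, so the build behind the values is uncertain. How a gene's length entered its FPKM, the annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart. FPKM values depend on the length used for each gene and on the sum over all genes, so a change in abundant genes shifts the rest. Whole reads could not be recovered from the values, and no count model was fitted. In each low gene, the ratio between samples takes repeated values when reads are few, and the most frequent ratio among genes under 0.05 FPKM (48 to 57 of 305 to 354 genes in its window) gave the relative depth. Because absolute depth is unknown, no counting interval or detection limit is given. The 10 most abundant genes held 6.97% to 7.20% of the FPKM sum. None of 12 housekeeping genes was at 0 in any sample, and 3 tested genes were at 0 in at least 1 sample. No pair of samples of a group shared a nonzero value. The table has no symbol beginning with mt-, and mitochondrially encoded genes were not analysed here.

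Genes with a mean of at least 1 FPKM over the 6 samples were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment over 9936 genes and a threshold of 0.05. Fold changes on this scale understate the change of low genes; folds of mean FPKM carry no pseudocount. Of 34 fixed gene lists, 27 had at least 5 tested genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry, whose mixed form passed for 26 lists, were run beside it. Counts of changed list members are over all genes tested, and those adjusted over the list alone stand beside them. The groups, tests, gene lists, markers and alternatives were fixed before the data were examined.

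The genes named were chosen by a rule. It takes the 10 largest rises and 10 largest falls among protein-coding genes with an adjusted p under 0.05 and groups that do not overlap, up to 4 passing members with the largest changes in each list (or 2 tested members where none passed), and 18 genes of osteoclasts, NRF2, iron and senescence whatever their values. Some list members taken by the rule are given only in the counts, and some are not reported here. Biotypes, transcript lengths and coordinates come from GENCODE mouse release M21 (GRCm38), matched by symbol and not used to make the values.

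The procedure was tested on simulated data with the levels and spread of the 9936 genes and 50 genes changed at each of 4 sizes. It called 28% of genes changed by 0.25 on the log2 scale with the right sign, 72% at 0.5, 98% at 1 and 100% at 2, with 9 false calls among 158. With no change simulated it called 0 genes and 0 lists, and a list shifted by itself was the 1 list called. All tested genes of that list were shifted by 0.3 in 1 direction. Lists called in the real data had medians as small as -0.09, with genes moving both ways, so power at such sizes was not shown. The noise of each gene was simulated independently, while estimated correlations in the real lists reached 0.364 (ribosomal proteins). The simulation therefore does not show how often lists of correlated genes are called falsely.

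Alternatives were other pseudocounts (0.1 and 5), no filter or a filter at 5 FPKM, rescaling each sample to the same sum (as TPM), median-ratio scaling, quantile normalization, other variance priors, the replicate number as a block, and leaving out each sample in turn. A fit of the 9794 tested genes that GENCODE annotates as protein coding was added after seeing the data.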

Results

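Gene expression was measured by RNA sequencing in RAW264.7 cells, a mouse macrophage-like line that can be driven to form bone-resorbing osteoclasts. All 6 samples come from cells put under osteoclast-inducing conditions. Cells of 3 samples received the solvent DMSO, and those of the other 3 received neobavaisoflavone (NBIF), a plant isoflavone, at 8 µM. The table analysed holds FPKM values (fragments per kilobase of transcript, scaled to the number of fragments sequenced) for 20938 mouse genes, of which 5790 were at 0 in all 6 samples. Between 13073 and 13415 genes were above 0 in a sample, and the FPKM values of a sample summed to between 484603 and 494172. The total number of reads is unknown from such values, but the steps between low values put the relative depth of the samples at 0.886 to 1.08 times that of DMSO 1. The logged values correlated at 0.993 to 0.996 within a group and at 0.986 to 0.989 between groups. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

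The comparison of NBIF with DMSO addresses how the compound acts on cells forming osteoclasts, and the title of the study names Nrf2, iron homeostasis and senescence. With NBIF, 18 of 25 tested genes of macrophage identity, 12 of 29 of osteoclast differentiation and resorption and 23 of 41 of oxidative phosphorylation fell, and 17 of 20 endoplasmic reticulum chaperone genes rose, each at a limma adjusted p under 0.05. The matrix metalloproteinase gene Mmp9 fell from 224 ± 15.2 to 60.4 ± 5.70 FPKM (mean ± SD, n = 3 per group). The lysozyme gene Lyz2 fell from 746 ± 74.1 to 157 ± 9.40 FPKM. The iron exporter gene Slc40a1 (ferroportin) rose from 6.62 ± 0.45 to 20.3 ± 1.60 FPKM, a 3.07-fold rise. Nfatc1, which encodes a master transcription factor of osteoclast formation, rose from 139 ± 38.6 to 286 ± 8.18 FPKM.

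Of 9936 genes tested, 1850 (18.6%) changed at an adjusted p under 0.05, of which 1047 were higher and 803 lower with NBIF (56.6% higher). After median-ratio scaling the split was 692 higher and 1013 lower (40.6% higher), and without NBIF 1 it was 493 and 506 (49.3% higher). The balance of directions therefore depends on the scaling and on the samples used. Most changes were small, with a median absolute log2 change of 0.33 among changed genes, and 61 genes changed at least 2-fold, 17 higher and 44 lower. The groups did not overlap for 3871 tested genes (39.0%), where chance gives 10%. The number of changed genes was 1173 without DMSO 1, 999 without NBIF 1, and 1150 without NBIF 2 as well as without NBIF 3. The 2-fold count was 105 with a pseudocount of 0.1, 26 with a pseudocount of 5 and 37 among genes with a mean of at least 5 FPKM.

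**Figure D1:**
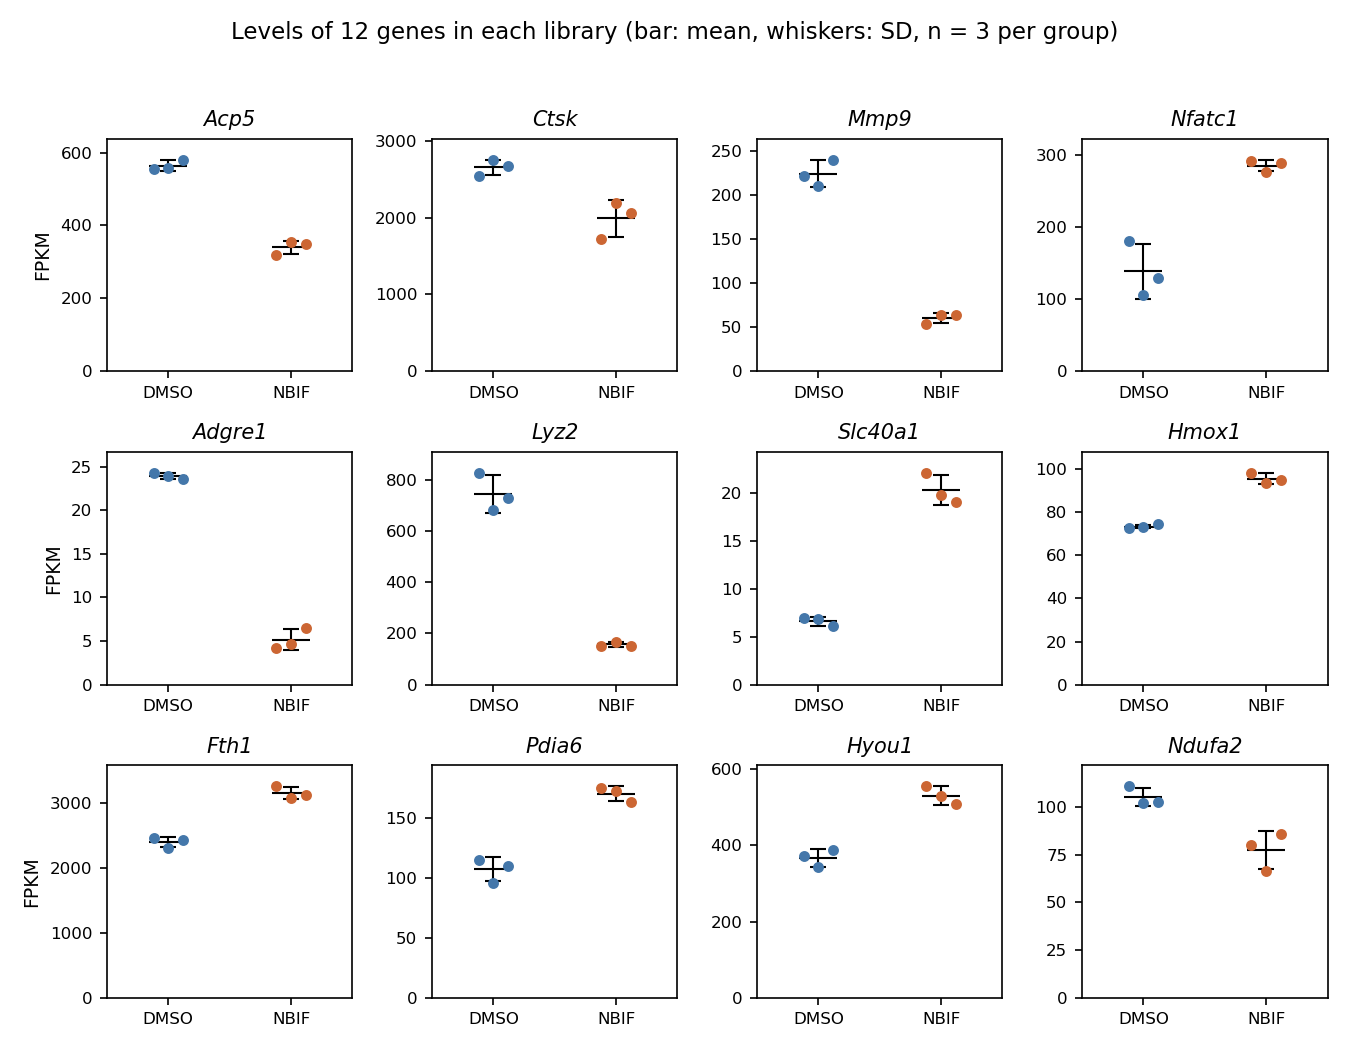
FPKM (vertical axes, each starting at 0) of 12 genes in each DMSO and NBIF library, with points for the 3 libraries of a group, a bar for the mean and whiskers for the SD. For every gene shown the 3 NBIF libraries lie on one side of the 3 DMSO libraries, and Nfatc1 has its widest spread in DMSO, with an SD of 38.6 FPKM against 8.18 FPKM in NBIF.

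Among the 10 protein-coding genes with the largest rises, Selp (P-selectin, a cell adhesion receptor; chromosome 1, 164115264 to 164150026 in GRCm38) went from 60.4 ± 3.58 to 334 ± 16.4 FPKM, a log2 change of 2.45 ± 0.06 (SE; limma adjusted p = 3.01e-07). Vtcn1, an inhibitory ligand of the B7 family, rose by 2.15 on the log2 scale, Fam83g by 1.61, Slc40a1 (chromosome 1, 45908068 to 45926523) by 1.48 and the costimulatory receptor gene Cd40 by 1.36. The antigen presentation genes H2-Eb1 and H2-K1 rose by 1.33 and 1.19, and Ltbp1, which encodes a binding protein of latent TGF-beta, by 1.26. The value of H2-K1 is uncertain, because it is close in sequence to other class I genes and the effect of mapping reads of this BALB/c-derived line to another strain was not tested, and its adjusted p was 0.0576 with a robust prior. Tirap rose by 1.32 and Tbcel went from 10.9 ± 6.86 to 23.7 ± 0.136 FPKM, both with a wide spread in DMSO. The adjusted p of Tirap was 0.0573 without DMSO 1, 0.0524 without NBIF 1, 0.0512 without NBIF 2, 0.0527 without NBIF 3, 0.0646 without a filter on low values and 0.0889 with a robust prior. That of Tbcel was 0.0815 without DMSO 2, 0.0698 without DMSO 3, 0.0805 without NBIF 1, 0.0755 without NBIF 2, 0.0778 without NBIF 3, 0.0923 without a filter and 0.136 with a robust prior.

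Among protein-coding genes that passed the test without overlap of the groups, the largest fall was that of the olfactory receptor gene Olfr933, from 9.74 ± 1.38 to 0.565 ± 0.0713 FPKM (log2 change of -2.77). Lyz1 fell by 2.54 on the log2 scale and Lyz2 by 2.24, and since these lysozyme genes are near-identical, as are Olfr933 and its neighbours, the values of single members are uncertain. The other log2 changes among the 10 largest falls were -2.06 for Aebp1, -2.03 for the macrophage surface gene Adgre1 (F4/80), -1.97 for the lectin receptor gene Clec4n, -1.90 for the fractalkine receptor gene Cx3cr1, -1.88 for Cd300ld and -1.87 for Mmp9, and the NADPH oxidase subunit gene Cybb fell from 16.3 ± 1.96 to 3.33 ± 0.214 FPKM. Genes near 1 FPKM are compressed by the pseudocount: Cx3cr1 went from 5.38 ± 0.433 to 0.749 ± 0.446 FPKM, and its log2 change was -2.87 with a pseudocount of 0.1 and -0.85 with a pseudocount of 5. With a pseudocount of 5, the log2 changes of Vtcn1 (1.14), Fam83g (0.86), Cd40 (0.77), H2-Eb1 (0.74), Tirap (0.77), Ltbp1 (0.66), Olfr933 (-1.40), Aebp1 (-0.94) and Clec4n (-1.23) also shrank by more than 1.5 times, and each call held. The same was seen for Pirb (-0.68), Jun (-0.29), Ephx1 (-0.61), Cxcl16 (-0.74), Parp14 (0.41), Irf7 (0.24), Clec7a (-0.998), Egr2 (-0.37), Acod1 (-0.35), Ube2c (-0.34) and Cenpf (-0.24), which are described with their lists, and with a pseudocount of 0.1 Irf7 was at 0.92 and Acod1 at -1.83.

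Of 27 gene lists tested with limma's camera at a preset correlation, 10 changed relative to other genes, 8 lower and 2 higher. Only macrophage identity passed with an estimated correlation. That form gave larger p-values even where the estimated correlation was below the preset one. For macrophage identity it was 0.00588, and the unadjusted camera p went from 2.64e-15 to 0.00117. A call lost this way therefore need not reflect correlation between genes. At least as many lists came from 3 of the 10 ways to split the 6 samples into 3 and 3, the real one included. All splits but the real one mix the treatments in both groups, so they still hold part of their difference. By fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, 11 lists passed.

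**Figure D2:**
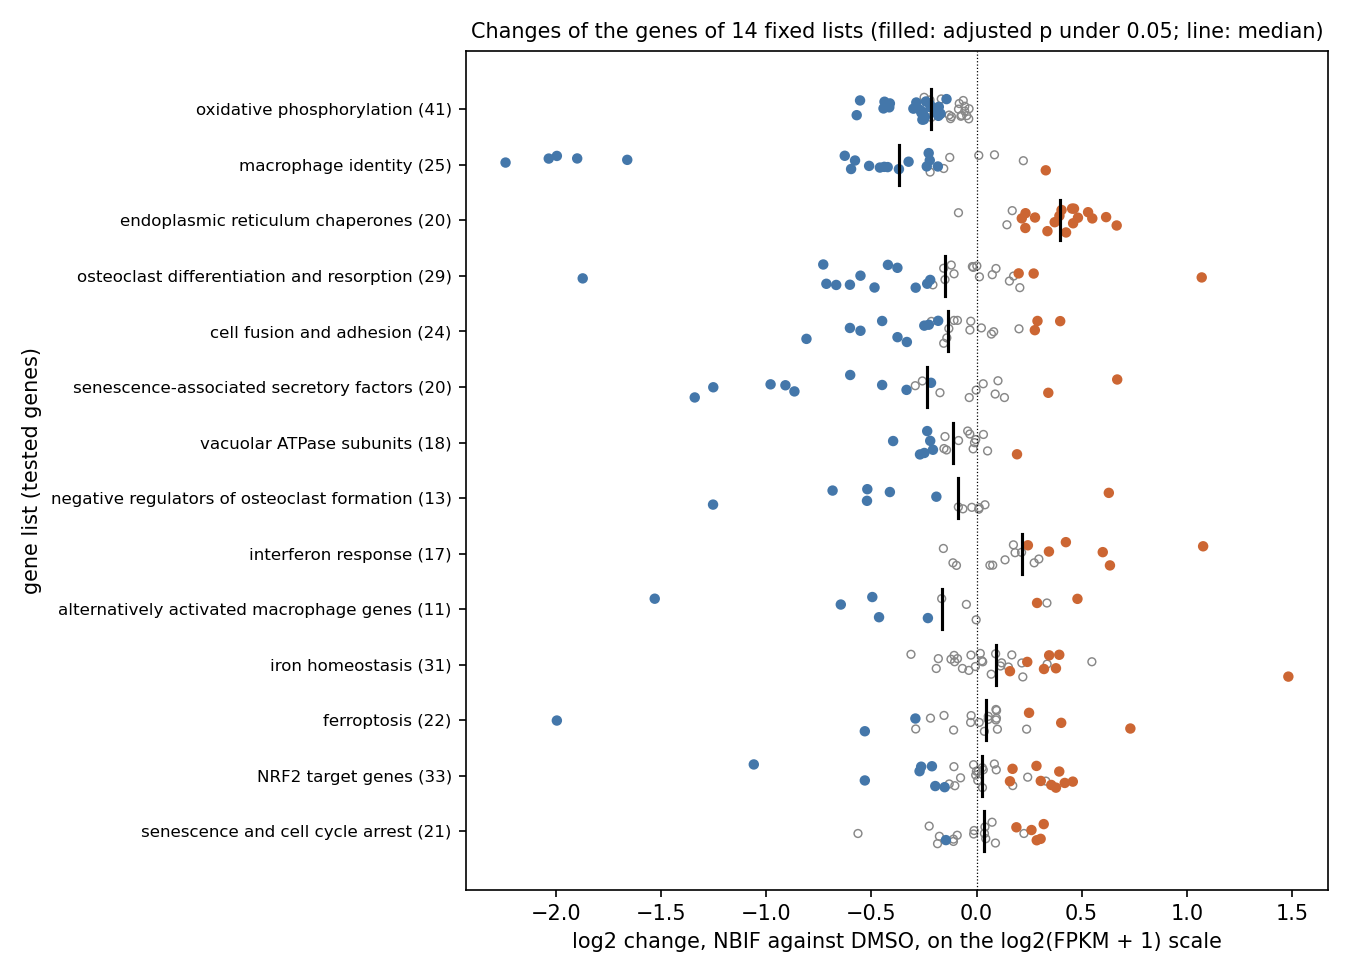
Log2 changes between NBIF and DMSO (horizontal axis, log2(FPKM + 1) scale) of the tested genes of 14 lists (vertical axis, number of genes in parentheses). Filled points have an adjusted p under 0.05, orange for higher and blue for lower with NBIF, open points do not, and the black line is the median, which runs from -0.37 for macrophage identity to 0.40 for endoplasmic reticulum chaperones.

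Of 29 tested genes of osteoclast differentiation and resorption, 12 fell, 3 rose and 14 did not pass the test (13 lower and 6 higher when adjusted over the list alone). The list was lower with a median log2 change of -0.15 (camera adjusted p = 6.10e-05; adjusted p = 0.406 with an estimated correlation). Acp5, which encodes the osteoclast enzyme tartrate-resistant acid phosphatase, fell from 564 ± 14.4 to 340 ± 18.5 FPKM, a log2 change of -0.73 ± 0.05 (SE, limma adjusted p = 5.16e-05). Ctsk, the collagen-degrading protease cathepsin K, fell from 2656 ± 100.2 to 1992 ± 240.1 FPKM, a log2 change of -0.42 ± 0.08 (adjusted p = 0.00910). The carbonic anhydrase gene Car2 fell by 0.71 on the log2 scale and Mmp9 (chromosome 2, 164940780 to 164955850) fell by 1.87. Nfatc1 (chromosome 18, 80606205 to 80713071) was among the 3 that rose, by 1.07 ± 0.16 (SE, adjusted p = 0.00283), and its DMSO libraries ranged from 105.6 to 181 FPKM. Dcstamp, needed for osteoclast fusion, had 59.9 ± 4.15 FPKM in DMSO and 53.7 ± 2.40 in NBIF (adjusted p = 0.118). The proton pump subunit gene Atp6v0d2 had 4116 ± 298 and 3706 ± 167 FPKM (log2 change of -0.15, adjusted p = 0.111). Its log2 change was -0.20 without DMSO 3 (adjusted p = 0.0367), -0.10 without DMSO 2 (0.269) and -0.02 after quantile normalization (0.782).

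Among 24 tested genes of cell fusion and adhesion, 9 fell, 3 rose and 12 did not pass (10 lower and 3 higher adjusted over the list alone; median -0.14, camera adjusted p = 0.000283, adjusted p = 0.131 with an estimated correlation). The metalloprotease gene Adam8 fell by 0.81 on the log2 scale, the fusion gene Ocstamp by 0.60, the tetraspanin gene Cd9 by 0.55 and Spp1 (osteopontin) by 0.45. Of 18 vacuolar ATPase subunit genes, whose products acidify lysosomes and the resorption pit, 6 fell, 1 rose and 11 did not pass (7 lower and 1 higher adjusted over the list alone; median -0.11, camera adjusted p = 0.000986, adjusted p = 0.406 with an estimated correlation). Atp6v0a1 fell by 0.40. The median of the subunit genes was -0.07 without DMSO 2, and after quantile normalization it was -0.00786 and the call was lost (camera adjusted p = 0.386). Among 13 tested negative regulators of osteoclast formation, 6 fell, 1 rose and 6 did not pass, counts that were equal when adjusted over the list alone (median -0.09, camera adjusted p = 0.00181, adjusted p = 0.131 with an estimated correlation). The inhibitory receptor genes Pirb and Lilrb4a fell by 1.25 and 0.68, and the transcriptional repressor gene Bcl6 by 0.52. The median of the negative regulators was -0.16 without DMSO 3 and -0.14 among genes with a mean of at least 5 FPKM. The 35 tested genes of RANK and NF-kB signalling, the pathway that starts osteoclast formation, did not shift as a list (median 0.01, mean -0.00270, camera lower, adjusted p = 0.315), with 5 lower and 1 higher, also when adjusted over the list alone. The adaptor gene Tyrobp fell by 0.54, the coactivator gene Ppargc1b by 0.53 and Jun by 0.46, and Fosl2 rose by 0.46.

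Of 25 tested macrophage identity genes, 18 fell, 1 rose and 6 did not pass (19 lower and 1 higher adjusted over the list alone). Their median log2 change was -0.37 (camera adjusted p = 3.57e-14; adjusted p = 0.0317 with an estimated correlation). Adgre1 went from 23.9 ± 0.363 to 5.16 ± 1.22 FPKM, and Lyz2, Cybb and Cx3cr1 were also among those that fell. Among 11 tested genes of alternatively activated macrophages, 5 fell, 2 rose and 4 did not pass, also when adjusted over the list alone (median -0.17, camera adjusted p = 0.0326, adjusted p = 0.224 with an estimated correlation). The beta-glucan receptor gene Clec7a fell by 1.53, Egr2 by 0.65 and the scavenger receptor gene Msr1 by 0.50, and the transglutaminase gene Tgm2 rose by 0.48. The list call was lost without DMSO 3 (camera adjusted p = 0.0551), without NBIF 1 (0.0506), without a filter (0.0520), after median-ratio scaling (0.0599), after quantile normalization (0.0617) and among genes annotated as protein coding (0.140; an alternative chosen after seeing the data, which leaves out Clec7a, annotated as a polymorphic pseudogene). The median of the list was -0.04 without a filter, -0.27 without DMSO 2 and -0.08 without NBIF 3. Of 9 tested genes of classically activated macrophages, from a list of 26, 4 rose, 1 fell and 4 did not pass (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.457). Genes below the filter are not covered, such as Nos2 (0.583 ± 0.0931 FPKM in DMSO, 0.0905 ± 0.0688 in NBIF) and Saa3 (0.212 ± 0.0997 and 0.335 ± 0.103). Cd40 and the cytokine subunit gene Il23a rose, by 1.36 and 0.88, and Acod1, the itaconate-making enzyme, fell by 0.99.

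The NRF2 target genes, which serve antioxidant and detoxifying functions, did not shift as a list. Of 33 tested, 9 rose, 7 fell and 17 did not pass (11 higher and 7 lower adjusted over the list alone; median 0.03, camera adjusted p = 0.921). The heme oxygenase gene Hmox1 rose from 73.4 ± 0.860 to 95.6 ± 2.41 FPKM, the catalase gene Cat by 0.46 on the log2 scale and the transporter gene Abcc4 by 0.42. The epoxide hydrolase gene Ephx1 fell by 1.06, and Slc7a11, the cystine importer subunit, fell from 53.3 ± 6.51 to 36.4 ± 1.27 FPKM. Gclm, a subunit of the glutathione-making ligase, had 17.1 ± 0.422 FPKM in DMSO and 18.4 ± 2.05 in NBIF (adjusted p = 0.444). Nfe2l2, which encodes NRF2, had 8.49 ± 0.725 and 8.57 ± 0.604 FPKM (adjusted p = 0.927), and Keap1, its inhibitor, 20.6 ± 2.59 and 20.5 ± 1.23 FPKM (adjusted p = 1.00). The quinone reductase gene Nqo1, a common NRF2 readout, lay below the filter at 0.213 ± 0.0462 FPKM in DMSO and 0.164 ± 0.0812 in NBIF and was not tested.

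Of 31 tested genes of iron homeostasis, 7 rose, 0 fell and 24 did not pass (10 higher and 1 lower adjusted over the list alone). As a list they did not shift relative to other genes (median 0.09 against 0.04 for all tested genes, camera adjusted p = 0.137). The fry test, which makes no such comparison, gave an adjusted p of 0.00237 for a rise. Besides Slc40a1, the ferritin heavy chain gene Fth1 rose from 2395 ± 78.7 to 3146 ± 92.3 FPKM and Bach1, a repressor of heme-regulated genes, from 24.9 ± 0.116 to 31.9 ± 0.654 FPKM. The transferrin receptor gene Tfrc had 300.6 ± 22.1 FPKM in DMSO and 333.9 ± 20.6 in NBIF (adjusted p = 0.147). The ferroptosis list, on iron-dependent lipid peroxidation, had 3 genes higher, 3 lower and 16 not passing among 22, also when adjusted over the list alone (camera adjusted p = 0.563; median 0.05, mean -0.06). The P450 reductase gene Por rose by 0.73, and Cybb and Slc7a11 fell.

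Genes of senescence and cell cycle arrest did not shift as a list: of 21 tested, 5 rose, 1 fell and 15 did not pass, also when adjusted over the list alone (median 0.04, camera lower, adjusted p = 0.921). Cdkn1a (p21) went from 126.0 ± 3.40 to 113.8 ± 1.11 FPKM (log2 change of -0.15, adjusted p = 0.0445), and Trp53 (p53) from 29.3 ± 1.42 to 33.5 ± 1.18 FPKM (0.19, adjusted p = 0.0475). These calls are fragile: that of Cdkn1a was lost without DMSO 1 (adjusted p = 0.0983), DMSO 2 (0.106), NBIF 1 (0.143), NBIF 2 (0.0955) and NBIF 3 (0.129), and that of Trp53 without DMSO 1 (0.143), DMSO 2 (0.110), NBIF 1 (0.0757), NBIF 2 (0.139) and NBIF 3 (0.145). They were also lost after quantile normalization, at 0.0595 and 0.0870, and without a variance trend, at 0.0877 and 0.0633. Cdkn1a further missed the threshold after rescaling samples to the same sum (0.0662), and Trp53 after median-ratio scaling (0.112) and without a filter (0.0625). The p53 target gene Zmat3 rose by 0.26, and Cdkn2a (p16) was listed at 0 in all 6 libraries. The tested secretory factors associated with senescence, 20 of the 42 on the list, were lower: 9 fell, 2 rose and 9 did not pass, also when adjusted over the list alone (median -0.24, camera adjusted p = 0.000986, adjusted p = 0.136 with an estimated correlation). The result does not cover the factors below the filter. Among them were Il6 (highest value 0.0136 FPKM), Il1b (0.400 FPKM), and Cxcl1 and Mmp3, both at 0 in all 6 libraries. The chemokine genes Ccl3 and Cxcl16 fell by 1.34 and 1.25 and the urokinase gene Plau by 0.91. The median of the secretory factors was -0.14 with a pseudocount of 5 and -0.06 without a filter, with the call kept in both.

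Endoplasmic reticulum chaperone genes rose, with 17 of 20 tested higher, 0 lower and 3 not passing (18 higher adjusted over the list alone). Their median log2 change was 0.40 (camera adjusted p = 1.13e-09; adjusted p = 0.131 with an estimated correlation). The disulfide isomerase gene Pdia6 rose from 107.1 ± 10.04 to 170.1 ± 6.15 FPKM, Hyou1 from 367 ± 23.2 to 530.0 ± 23.8 FPKM and Sdf2l1 from 13.3 ± 1.07 to 20.9 ± 0.784 FPKM. Of 41 oxidative phosphorylation genes, 23 fell, 0 rose and 18 did not pass (27 lower adjusted over the list alone; median -0.22, camera adjusted p = 3.27e-14, adjusted p = 0.122 with an estimated correlation). The respiratory complex genes Ndufa1, Ndufa2 and Cox5b fell by 0.55, 0.44 and 0.44. Among 17 tested interferon response genes, 6 rose, 0 fell and 11 did not pass (8 higher adjusted over the list alone; median 0.21, camera adjusted p = 0.00546, adjusted p = 0.406 with an estimated correlation). The antiviral synthetase gene Oas3 rose from 5.24 ± 0.451 to 12.2 ± 1.14 FPKM, Parp14 by 0.63 on the log2 scale and the transcription factor gene Irf7 by 0.60. Without a filter on low values the median of the interferon list was 0.06 and its call was lost (camera adjusted p = 0.113), and with a pseudocount of 5 the median was 0.13. The list has 39 genes, and those below the filter included Isg15, Ifit1 and Rsad2. Their highest values in any library were 0.375, 0.143 and 0.113 FPKM. Means below the filter went both ways: Isg15 had 0.321 FPKM in DMSO and 0.176 in NBIF, and Dhx58 0.334 and 0.557. Of 12 tested genes with the symbol stem Ifi, a family looked at after the results were seen, 4 fell and 0 rose (camera adjusted p = 0.188 over symbol families).

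The other lists did not pass. Of 13 tested LXR target genes, 3 fell and 0 rose (camera adjusted p = 0.0544), led by the phospholipid transfer gene Pltp, which fell by 1.14. This list passed without DMSO 1 (0.00726), DMSO 2 (0.0422), NBIF 2 (0.0373) or NBIF 3 (0.0483). Among 15 PPAR target and lipid storage genes 3 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.541): the fatty acid uptake gene Cd36 fell by 1.28 and the lipase gene Lpl by 1.07, and the lipid droplet gene Plin2 rose by 0.57. Cholesterol synthesis had 4 of 25 lower and 1 higher (0.0609, and 0.0108 without DMSO 1 and 0.0277 without NBIF 2). Glycolysis had 7 of 21 lower and 1 higher, or 7 and 2 adjusted over the list alone (0.0821, and 0.0495 without DMSO 1). Ribosomal protein genes had 3 of 36 lower and 0 higher, or 1 and 0 adjusted over the list alone, with a median of -0.03 and a mean of 0.00681 (0.0757, and 0.0443 without DMSO 2, 0.0234 without NBIF 1, 0.0121 without NBIF 3 and 0.0226 after median-ratio scaling). DNA replication had 4 of 33 lower and 1 higher (0.139, and 0.0422 without DMSO 2), and the mitotic cell cycle 3 of 22 lower and 1 higher (0.470), among them Ube2c and Cenpf, which fell by 0.64 and 0.54. Lysosome and TFEB targets had 3 of 31 higher and 4 lower, or 4 and 4 adjusted over the list alone (0.921): the protease genes Ctsd and Ctss rose by 0.38 and 0.37. The ATF4 list had 5 of 31 higher and 4 lower (0.921), hypoxia 1 of 18 higher and 1 lower, or 1 and 0 adjusted over the list alone (0.921), and heat shock 3 of 15 higher and 1 lower (0.845). For the LXR, cholesterol, DNA replication, mitotic, ATF4 and heat shock lists the counts adjusted over the list alone were the same. The median was above 0 and camera's direction lower for the RANK signalling, DNA replication, mitotic, PPAR, ferroptosis, lysosome, ATF4, hypoxia and senescence arrest lists, with the mean also above 0 for the ATF4, hypoxia and senescence arrest lists. Camera compares a list with other genes, and the median log2 change of all tested genes was 0.0439. Only 4 AhR target genes were expressed above the filter, of which 1 was higher, and they were not tested as a list.

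No marker of osteoblasts and fibroblasts, of lymphocytes, or of neutrophils and mast cells passed the expression filter, and the highest values of any library were 0.902, 0.262 and 0.309 FPKM. Of 15 endothelial, epithelial and erythroid markers 1 was tested and did not change. Of 13 dendritic cell markers 4 were tested and 2 rose: Cd74, the invariant chain of class II antigen presentation, from 401 ± 17.6 to 528 ± 24.6 FPKM, and H2-Eb1 from 2.19 ± 0.419 to 7.01 ± 0.439 FPKM. Below the filter and untested, H2-Aa went from 0.374 ± 0.213 to 1.62 ± 0.210 FPKM and H2-Ab1 from 0.0646 ± 0.0626 to 0.378 ± 0.0635. The marker Clec9a went the other way, from 0.869 ± 0.0285 to 0.407 ± 0.0715 FPKM.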

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

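The direction of the named genes with a call and of the 10 lists with a call held under the alternatives run. Among named genes, 1452 values under alternatives kept direction and side of the threshold, 34 lost a call, 1 gained one and 12 changed sign. Among lists, 409 kept both, 8 lost a call, 12 gained one and 30 changed sign, 1 of them with a call gained (DNA replication without DMSO 2). The number of changed genes ran from 999 (without NBIF 1) to 1891 (without DMSO 3) when 1 sample was left out, which leaves fewer samples to estimate the spread. It was 1497 without a filter, where more genes are adjusted for. The 2-fold count of 61 was 105 with a pseudocount of 0.1, 26 with a pseudocount of 5 and 37 with a filter at 5 FPKM, since a pseudocount compresses low genes and the filter removes them. The number of lists was 1 with an estimated correlation, and 9 to 13 when 1 sample was left out.

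Whether the replicate numbers pair the samples cannot be told. Deviations from the group means correlated at 0.0784, 0.126 and 0.0355 for numbers 1, 2 and 3. NBIF 2 and NBIF 3 correlated best with their own number, and NBIF 1 with DMSO 3 (0.0974). With the replicate block 1632 genes, 67 of them 2-fold, and 11 lists were called. Among named genes and lists, it ended the calls of Cdkn1a (adjusted p = 0.0844) and Trp53 (0.0651) and added that of the LXR targets (0.025).

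The values that changed sign belonged to 2 genes and 12 lists with no call in the comparison of all 6 samples. Median-ratio scaling took the median log2 change of all tested genes from 0.0439 to 0.00567. The small positive values that changed sign with it shared this downward shift. For the other settings the cause was not tested. With median-ratio scaling the log2 change of Nfe2l2 was -0.0255 and that of Keap1 -0.0406, with quantile normalization -0.0299 and -0.0350, and Keap1 was at -0.000527 with a pseudocount of 5. Leaving out 1 sample gave -0.0370 to 0.0744 for Nfe2l2 and -0.0786 to 0.0911 for Keap1. Among list medians, median-ratio scaling gave -0.0296 for RANK and NF-kB signalling, -0.0146 for NRF2 targets, -0.00167 for senescence and arrest, -0.0325 for DNA replication, -0.0335 for PPAR targets, -0.00480 for ATF4 and -0.00621 for hypoxia. A filter at 5 FPKM gave -0.0117 for senescence and arrest, -0.0325 for the mitotic cell cycle, -0.00148 for DNA replication and -0.0147 for PPAR targets. Quantile normalization gave -0.00392 for the mitotic cell cycle, -0.0435 for DNA replication, -0.0249 for PPAR targets and 0.0103 for ribosomal proteins. DNA replication was at -0.000861 with a pseudocount of 5, classically activated macrophages at -0.0120 without a filter and cholesterol synthesis at 0.00873 with samples rescaled to the same sum. Leaving out 1 sample gave -0.0148 to 0.0242 for RANK signalling, -0.0268 to 0.0679 for ferroptosis, -0.0108 to 0.0387 for senescence and arrest, -0.0204 to 0.0446 for the mitotic cell cycle, -0.0460 to 0.0131 for DNA replication, -0.0633 to 0.0126 for cholesterol synthesis, -0.0218 to 0.0434 for PPAR targets and -0.0496 to 0.00630 for ribosomal proteins.

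Voom on recovered reads was not run because whole reads could not be recovered, and a fit of protein-coding genes by a biotype in the table was not run because the table gives none. With GENCODE biotypes, an alternative chosen after seeing the data that leaves out Clec7a, 1839 genes, 59 of them 2-fold, and 9 lists were called. The depth of these libraries is unknown, so it is not known how far it limits the calls of low genes.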

Other observations

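The families and import genes described here, and the tests of residual macrophages and of other cell types, were chosen only after the results were seen. Genes that bring proteins into the endoplasmic reticulum (signal recognition particle, its receptor, the translocon and signal peptidase), none of them on the chaperone list, also rose: 13 of 20 were higher with NBIF and 0 lower, with a median log2 change of 0.27. The signal sequence receptor gene Ssr1 rose by 0.49 ± 0.07 (SE, limma adjusted p = 0.00285), Sec61a1 by 0.46 ± 0.04 (0.000241) and Srprb by 0.47 ± 0.06 (0.00186). The median lay at percentile 100 of 10000 random lists matched on mean level, whose central 95% ran from -0.06 to 0.11. Because these genes were picked after they were seen to rise, and random lists ignore correlation between genes, this percentile does not test a joint rise. Camera with an estimated correlation gave an unadjusted p = 0.0446 for them, and an adjusted p = 0.972 for the symbol families Srp and Sec. With median-ratio scaling the count was 10 and with quantile normalization 11.

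Of 11 tested genes with the symbol stem Clec, most of which encode C-type lectin receptors, 8 fell, 0 rose and 3 did not pass, with a median log2 change of -0.62 (adjusted p = 0.972 with an estimated correlation). Clec5a fell by 0.94, Clec4d by 0.79, Clec4e by 0.72 and Clec12a by 0.59. Of 16 tested H2 genes, most of which present antigens, 7 rose, 0 fell and 9 did not pass, with a median of 0.43 (adjusted p = 0.972 with an estimated correlation). Besides H2-K1 and H2-Eb1, H2-Q4 rose by 0.63 and H2-D1 by 0.27 (adjusted p = 0.0128, and 0.0518 without NBIF 1). Reads shared among near-identical members leave these values uncertain, and the effect of mapping reads of this BALB/c-derived line to the reference of another strain was not tested. Both counts were equal under the 3 other scalings. Of 314 symbol families 13 passed camera with the preset correlation, and 0 passed with an estimated one, so a joint shift of a family relative to other genes was not shown.

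The counts were also taken in the other splits of the samples. The real split gave 1850 changed genes, and the highest of the other 9 splits gave 2. For 2-fold changes these were 61 and 2. The real split was the 1 split with as many genes in both cases. For lists, the real split gave 10, the highest other split 15 (DMSO 1, NBIF 1 and NBIF 3 against the rest) and another 12, so 3 of the 10 splits gave as many. With 10 splits no share under 0.05 can be reached. Each of the other 9 splits also puts DMSO and NBIF samples in both of its groups. Part of a treatment difference then stays between the groups, and part widens the spread within them. These splits therefore do not show how many genes or lists would be called without a treatment difference.

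Of 41 oxidative phosphorylation genes 23 fell with NBIF (adjusted p = 0.122 for the list with an estimated correlation), and 2 technical explanations were set against this. Their transcripts are short (median of the longest transcript 1445 nt against 3420 nt for all tested genes), and the shortest length decile of genes had a median log2 change of -0.02 where the other deciles had 0.03 to 0.07. The list median of -0.22 lay at percentile 0 of 10000 lists matched on length and level, whose median was -0.02 and whose central 95% ran from -0.09 to 0.04. The gap between these medians argues against length as the whole cause. The percentile is no p-value, because random lists ignore correlation between genes. The length is that of the longest annotated transcript and may differ from the length used for the FPKM values. The 3 NBIF libraries had list medians of -0.19, -0.20 and -0.18 against the DMSO mean, so no single library set it. An effect of NBIF on these genes remains a hypothesis, found and tested on the same samples.

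Nfatc1 was higher with NBIF, and 12 of 29 genes of osteoclast differentiation and resorption were lower. Leaving out each library in turn gave log2 changes from 0.89 to 1.28, with adjusted p-values of at most 0.0148, which argues against 1 library as the cause. Its SD within DMSO (0.39 on the log2 scale) lay at percentile 99.0 of the 500 genes nearest in level, and its SD within NBIF (0.04) at percentile 50.2. The annotation gives Nfatc1 7 transcripts, and because the spread is wide in 1 group only, uneven estimates of such a gene cannot be told apart from a difference in its regulation.

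Macrophage identity genes (18 of 25) and osteoclast genes (12 of 29) fell with NBIF, and only the macrophage list kept its call with an estimated correlation (adjusted p = 0.0317, and 0.406 for the osteoclast list). More undifferentiated macrophages left with NBIF would put the median of the macrophage genes above 0. It was -0.37 (bootstrap 95% interval over 25 genes -0.58 to -0.22), with 18 genes lower and 1 higher. This fall was known before the test was set, so the median is no independent test of this cause, and it does not bear on the osteoclast genes. The interval ignores correlation between genes. Fibroblasts, osteoblasts, lymphocytes, neutrophils or mast cells would bring their abundant transcripts, but of 44 markers of these cells the highest in an NBIF library was Runx2 at 0.675 FPKM. Dendritic cells in a share that lowers macrophage genes this far would bring class II chain genes, among their most abundant transcripts. With NBIF H2-Aa was at 1.62 ± 0.210 FPKM (0.374 ± 0.213 with DMSO) and H2-Ab1 at 0.378 ± 0.0635 (0.0646 ± 0.0626 with DMSO). The highest value of these genes and H2-Eb1 in an NBIF library was 7.35 FPKM. These levels argue against dendritic cells rich in class II as the cause, though the limit was set after the values were seen. Cells poor in class II are not covered. All samples are labelled as 1 cell line, so low markers of other cells were likely whatever lowered the macrophage genes. Undifferentiated macrophages stay open for the fall of the osteoclast genes, and a different state of the treated cells stays open for both lists.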
